A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

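BrdU-labelled DNA and input DNA of fission yeast were measured on 4 2-colour Agilent tiling arrays, 2 of them labelled wild type and 2 labelled fft3Δ, each group with an array of series 1 and an array of series 2. Per the labels' protocols, DNA was sheared to 500 to 1000 bp, immunoprecipitated with an anti-BrdU antibody, amplified from random primers and labelled with Cy5, while whole-cell extract DNA was amplified alike and labelled with Cy3. All 4 arrays had this orientation, with no dye swap, so dye bias does not cancel within a group. The submitters' processing notes name Agilent Feature Extraction. Per the file headers its version was 12.0 for 3 arrays and 11.5 for wild-type array 2. The array statistics of the headers record background subtraction and a linear dye normalization factor for each channel. They give no genome build.

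The deposited scanner files hold processed signals of each channel, as intensity values, background-subtracted and dye-normalized by Agilent's software per the file headers, beside median and background intensity values. Their log ratio column is log10 of Cy5 over Cy3 per the file headers and was used only to check the direction. The deposited series matrix holds a linear ratio per spot. Set against the scanner values it was the processed Cy5 over the processed Cy3 signal of the same array, not centred, to within 0.013 on the log2 scale on wild-type array 2, whose file is rounded, and to within rounding elsewhere. The median of its columns was 1.03, 0.99, 1.07 and 1.02 for wild-type array 1, labelled fft3Δ array 1, wild-type array 2 and labelled fft3Δ array 2. The flag columns of the deposited files, of unit other, mark non-uniform, saturated and well-above-background spots.

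Of 42968 spots, 41551 were probes, each spotted once, 41251 of them on the 3 chromosomes, 110 on a separate mating-type contig, 61 on the mitochondrial contig and 129 on contigs named pNSU. Control spots were left out, as were spots with a non-uniformity flag, of which wild-type array 2 had 617 and the others 4 to 7. No probe was saturated. The log2 ratio of the processed signals was centred on each array's median, with no loess or quantile step, since most probes carry signal. Probes were averaged in windows of 2 kb with at least 3 probes, and windows and peaks were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05 and genotype as the only term. Regions were tested against all other windows with camera, at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 3 regions. Values per array were compared with the exact permutation test, two-sided, which cannot go below 0.33 with 2 arrays against 2. Files were read with the R package data.table, version 1.17.8, and figures were drawn with matplotlib 3.10.9.

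The positions printed are those of the array design, counted from 1. Its build was compared with the reference given (GenBank name ASM294v3). A probe position on chromosome 3 (2453700) lies past the end of that reference (2452883 bp). In blocks of 100 kb, the GC content of 60-base stretches of the reference followed the input signal best at a shift of -740 bp on the left arm of chromosome 1 and 4460 bp on its right arm, -860 and -1660 bp on chromosome 2, and 140 and -730 bp on chromosome 3, and 66.7% to 89.2% of the blocks of an arm lay within 300 bp of its median shift. The coordinates differ, no conversion was made, and no gene was placed on the array. The planned comparisons by gene, the gene lists and the genes fixed for naming were therefore not run, probes inside fft3 were not left out, and input differences were tested over 2 kb windows in place of genes. The fft3 gene's length was the only value taken from the annotation.

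Pericentromeres were 3750001 to 3800000 of chromosome 1, 1600001 to 1650000 of chromosome 2 and 1070001 to 1140000 of chromosome 3. The mating-type region was the array's own contig, and subtelomeres were the outermost 50 kb with probes on chromosomes 1 and 2. Peaks were the highest probe within 5 kb on each side of the mean of the 4 arrays, smoothed over probes within 500 bp, above a threshold in background SDs over the median. The background SD, from the smoothed probes below the median, was 0.73, and the planned threshold of 3 SDs (2.20) left 0 peaks, as did 5 SDs; 2 SDs left 12. A threshold of 1 SD (0.74) was chosen after these counts were seen and used for every peak result. A peak's value was the mean of the probes within 1 kb, and its width was cut off at 10 kb on each side.

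Before the data were examined, the tests, the alternatives and the rule for named items were fixed. By that rule the text names the 8 peaks with the largest rise and the 8 with the largest fall that had the same sign in both series, filled up by moderated t where they did not pass, the 5 tallest peaks, and the 3 windows over 5 kb from any peak with the largest rise and the 3 with the largest fall. The rule's genes were not placed, as above. The alternatives were normexp background correction (offset 50, on median signals, as the files used here hold no mean signal column), loess, scaling to a common SD, quantile normalization, centring on the mode, only probes well above background, the Cy5 signal alone, the series matrix, the series number as a block, the shared slide alone, each array left out, and other window sizes, peak rules and set test settings. Thresholds of 0.5 and 1.5 SDs, the chromosome 2 copy of the mating-type region, and the region tests without the probes whose names carry an f or m were added after the data were seen.

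Both arrays of series 1 share a slide and a scanner. The arrays of series 2 are on separate slides and share another scanner. A scanner block is thus the series block, and only series 1 gives a difference within a slide; both are printed. Pairing by series number was not treated as established, since the labels do not say that a number marks a shared day or batch.

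The fit was tested on simulated data drawn from the arrays' window means and fitted spread, with 200 of 6234 windows changed. It recovered 12.9% of the windows changed by 0.5, 95.1% of those changed by 1 and 100% of those changed by 2, with 11 false calls, and made 0 calls with no change. In simulated subtelomeres of 95 windows that shared an error of SD 0.15 per array, camera at the preset correlation called 68% of 100 unchanged regions and 100% of those shifted by 0.5, and with an estimated correlation 0% and 11%. The first is thus too lenient here and the second has little power. The measured SD of the subtelomere mean between arrays of a group was 0.26, above the simulated 0.15, so both can perform worse on these arrays. All 60 simulated peaks, placed on a flat profile and called at the planned threshold of 3 SDs, were recovered among 95 called. Part of the peaks called can thus be noise, and the median width of the recovered peaks was 4500 bp for a true width of 4000 bp. The simulated peaks were taller than any peak of the arrays, so these values do not carry over to the peaks called at 1 SD.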

Results

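Replication in fission yeast (Schizosaccharomyces pombe) was mapped by the uptake of bromodeoxyuridine (BrdU), a thymidine analogue, in cells that could not extend their forks freely. The cells carried cdc25-22, a temperature-sensitive allele of the phosphatase that starts mitosis, together with a viral thymidine kinase and a human nucleoside transporter that let them take up BrdU. They were held at 37 °C, released at 26 °C into 10 mM hydroxyurea, which starves forks of deoxynucleotides, with 200 µM BrdU, and collected at 120 min. DNA recovered with an anti-BrdU antibody was labelled with Cy5 and whole-cell extract DNA, the input, with Cy3, and both were hybridised to a 60-mer tiling array with a probe every 300 bp on average. The series held 4 arrays, 2 labelled wild type and 2 labelled as a deletion of fft3, the gene of a chromatin remodeller of the SNF2 family, in which a first and a second series each gave a single array per genotype. The series title names proper replication of the genome as an aim, so the comparison asked where BrdU incorporation differed without Fft3. Each array measured 41551 probes. The median Cy3 signal was 18.0 times the local background on wild-type array 1, 17.1 times on labelled fft3Δ array 1, 217 times on wild-type array 2 and 55.4 times on labelled fft3Δ array 2. With 2 arrays per group, the number of arrays limits the precision. The labels do not say whether the series were separate cultures, so p-values cannot be taken to measure more than the spread between these arrays. Those of limma also pool that spread over windows or peaks, and those of camera at the preset correlation rest on the spread over windows.

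In wild type, BrdU incorporation differed between regions and chromosomes. Signal was high at the pericentromeres, where 60 windows of 2 kb had a mean log2 ratio of immunoprecipitate over input of 0.66 ± 0.001 (SD, n = 2), against a median of 0 for all probes of an array. That SD hid opposite differences. Wild-type arrays 1 and 2 gave 0.64 and 0.54 on chromosome 1, 0.56 and 0.61 on chromosome 2, and 0.81 and 0.91 on chromosome 3. The outermost 50 kb of chromosomes 1 and 2, the subtelomeres, had the opposite level, at -1.54 ± 0.32 (SD, n = 2). The windows of chromosome 3, the shortest chromosome, averaged 0.32 ± 0.05 in wild type, above -0.17 ± 0.02 on chromosome 1 and -0.15 ± 0.001 on chromosome 2 (SD, n = 2 each). In the arrays labelled fft3Δ the corresponding means were 0.29, -0.17 and -0.13. A log2 ratio under -1 was found in 9.61% of the 2 kb windows of wild-type array 1 and 7.62% of those of wild-type array 2, and a ratio over 0.5 in 19.4% and 17.9%.

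**Figure D1:**
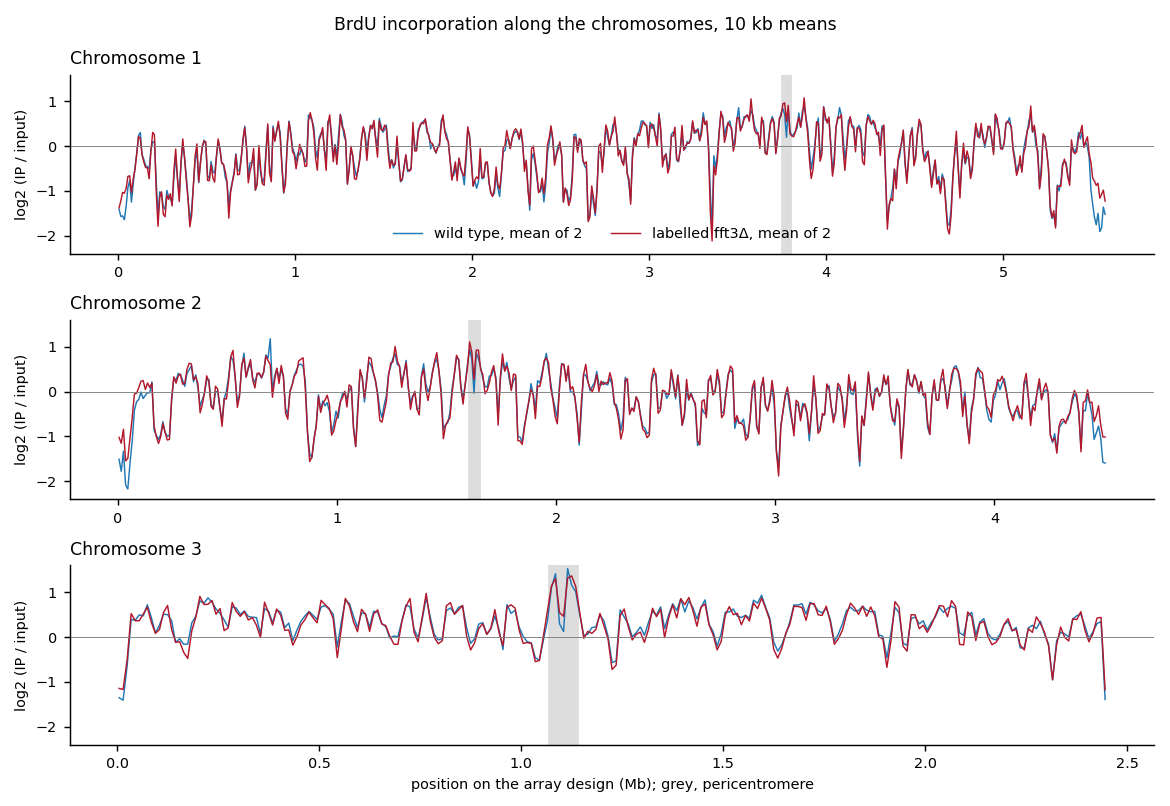
Mean log2 ratio of BrdU immunoprecipitate over input in 10 kb steps (y axis) along the 3 chromosomes (x axis, position on the array design in Mb), as the mean of the 2 wild-type arrays (blue) and of the 2 arrays labelled fft3Δ (red), with the pericentromeres shaded. The lines run together over most of each chromosome and part at the ends of chromosomes 1 and 2, where the subtelomeres averaged -1.54 in wild type and -1.03 in the arrays labelled fft3Δ.

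The deletion named in the labels was looked for first in the input. No probe was assigned to fft3, because the array's genome build is not named and its positions were not converted to the reference. Every stretch of the chromosomes was therefore examined for missing DNA. All 41251 chromosome probes were well above background in the input of all 4 arrays. The fft3 gene is 3611 bp long in the reference annotation and would span 12 adjacent probes. Among 41218 such runs, the lowest median difference in input between labelled fft3Δ array 1 and wild-type array 1, which share a slide, was -0.45 on the log2 scale. For labelled fft3Δ array 2 against the same wild-type array the lowest run was -0.65. In series 2 it was -1.38, against wild-type array 2, whose input had a narrower range (below). No run reached -1 or lower in both series, and the lowest value that a run reached in both was -0.28. The Cy5 signal gave -0.40 and -0.61 for the 2 arrays labelled fft3Δ against wild-type array 1. A loss of the gene from 50% of the DNA would lower the run by 1. A probe could read at background on these arrays, since 16 probes of the array's separate mating-type contig were not well above background in any input. As these lacked signal on all 4 arrays, absent DNA and probes that do not hybridise could not be told apart. A gene lying in 1 of the 3 gaps between probes that are longer than fft3, or a disruption that removed little DNA, would not have been seen. These values did not show the deletion that the label names, so the arrays are called "labelled fft3Δ" throughout, and every direction given below is that of the label.

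BrdU incorporation near the ends of chromosomes 1 and 2 was less depleted in the arrays labelled fft3Δ than in wild type. Over the 95 subtelomere windows the mean log2 ratio was -1.03 ± 0.18 in the arrays labelled fft3Δ and -1.54 ± 0.32 in wild type (SD, n = 2 each), a difference of 0.51. It was 0.41 within the shared slide of series 1 and 0.61 in series 2. The Cy5 signal alone differed by 0.27 (0.29 in series 1, 0.26 in series 2), and the input by -0.13 in series 1 and -0.41 in series 2. At the left end of chromosome 1 the ratio was -1.13 ± 0.14 against -1.504 ± 0.08, and at its right end -1.02 ± 0.11 against -1.67 ± 0.36. The left end of chromosome 2 gave -1.30 ± 0.15 against -1.88 ± 0.36, and its right end -0.72 ± 0.30 against -1.18 ± 0.47 (SD, n = 2 each). All 4 ends were higher in the arrays labelled fft3Δ in both series. Whether the ends share sequence was not examined, so they are not taken as independent. The difference was 0.36 in the outermost 10 kb, 0.58 between 40 and 50 kb from the end and 0.14 between 90 and 100 kb. The windows of chromosome 1 from 5546001 to 5548000, 5552001 to 5554000 and 5554001 to 5556000 (positions of the array design) had the largest moderated t of all windows over 5 kb from a peak, with differences of 0.70, 0.89 and 0.96, none past the adjusted threshold (adjusted p = 0.883 each, limma). With normexp background correction these were 0.44, 0.48 and 0.49, and with the Cy5 signal alone 0.44, 0.49 and 0.57. The left end of chromosome 3, a chromosome that ends in ribosomal DNA, differed by 0.29 in series 1 and -0.02 in series 2, and its right end by 0.15 and -0.02.

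Camera, the competitive set test of limma, called the subtelomeres at a preset correlation (adjusted p = 5.2e-48), and did not with an estimated correlation (adjusted p = 0.146). The spread between same-genotype arrays was large here, wild-type array 1 lying at -1.32 and wild-type array 2 at -1.77. The exact permutation test of the 4 array means gave p = 0.33, the smallest that 2 arrays against 2 allow. Without wild-type array 2, whose input stood apart (below), the difference was 0.29. None of 10000 draws of 4 stretches of the same length from the chromosome interiors reached the observed difference, the highest being 0.09. This describes these arrays and carries no replicate error.

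**Figure D2:**
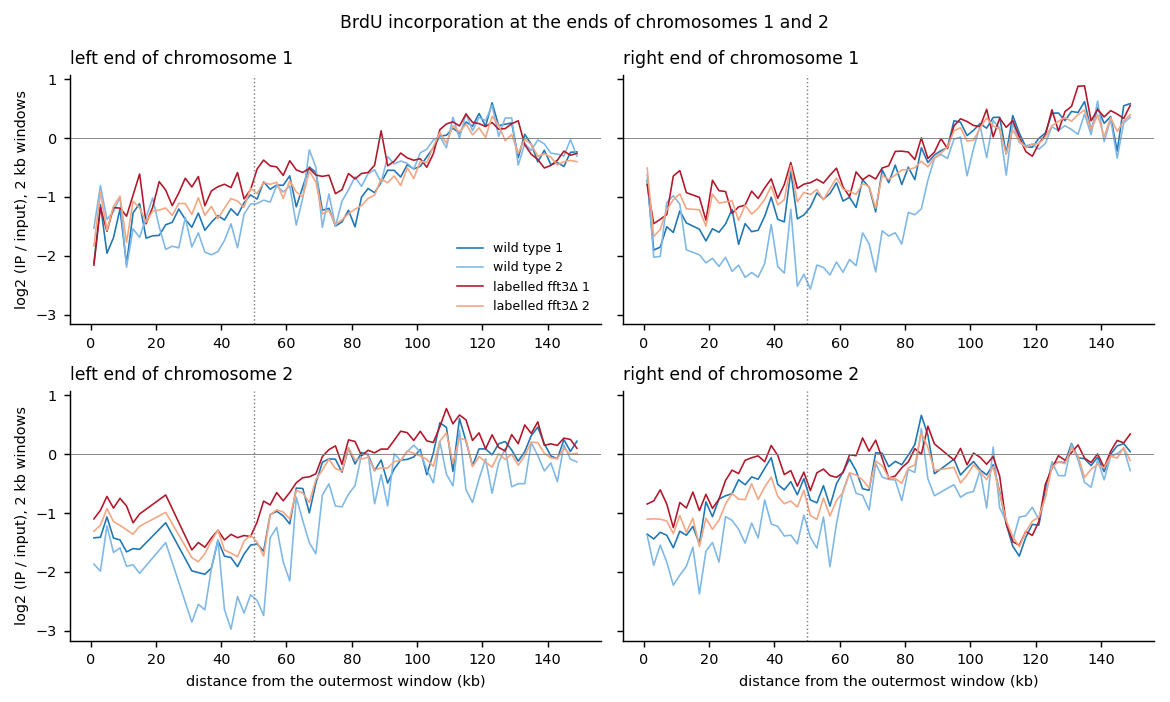
Log2 ratio of BrdU immunoprecipitate over input in 2 kb windows (y axis) against the distance from the outermost window (x axis, kb) at both ends of chromosomes 1 and 2, with a line per array (blue, wild type; red and orange, labelled fft3Δ) and a dotted line at 50 kb. Both arrays labelled fft3Δ had higher means than both wild-type arrays over the outermost 50 kb at 3 of the 4 ends; at the right end of chromosome 2 labelled fft3Δ array 2 (-0.94) lay below wild-type array 1 (-0.85).

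The pericentromeres, which hold the centromeric heterochromatin repeats and replicate early in this organism, had a mean log2 ratio of 0.82 ± 0.16 in the arrays labelled fft3Δ and 0.66 ± 0.001 in wild type (SD, n = 2 each, 60 windows). By chromosome the wild-type SD was larger, at 0.07, 0.03 and 0.07 for chromosomes 1, 2 and 3. The difference of 0.15 came mostly from series 1, where it was 0.26 within the shared slide; in series 2 it was 0.04. The Cy5 signal alone differed by 0.41, with the opposite split of 0.18 in series 1 and 0.64 in series 2. The input differed by -0.09 in series 1 and 0.54 in series 2, where it was 0.47 on wild-type array 2 and 1.01 to 1.17 on the others. The larger Cy5 difference of series 2 thus came with a larger input difference and is not read as a gain of BrdU. By chromosome the difference was 0.14 for chromosome 1, 0.20 for chromosome 2 and 0.11 for chromosome 3, and on chromosome 3 its sign differed between series 1 (0.24) and series 2 (-0.02). Camera called the region at the preset correlation (adjusted p = 1.5e-06) and not with an estimated correlation (adjusted p = 0.250). With normexp background correction the difference was 0.009, with centring on the mode 0.065, without labelled fft3Δ array 1 0.040, and without labelled fft3Δ array 2 0.26.

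The mating-type region, which also holds a block of heterochromatin, was measured on the array's own contig of 110 probes. Its 20 windows averaged 0.40 ± 0.09 in the arrays labelled fft3Δ and 0.18 ± 0.006 in wild type (SD, n = 2 each), with differences of 0.16 in series 1 and 0.28 in series 2. Over the 83 probes with input on all arrays the means were 0.46 ± 0.08 and 0.33 ± 0.11 (SD, n = 2 each), so the small wild-type SD did not hold there. Camera gave an adjusted p of 9.4e-05 at the preset correlation, and an adjusted p of 0.146 with an estimated correlation. The estimate here was 0.008, below the preset 0.01, so a higher correlation between windows is not why this call was lost. What else in that setting of camera lost it was not tested. The estimates were 0.23 for the pericentromeres and 0.51 for the subtelomeres. Part of this contig was not well above background in either channel, and with the probes well above background in both channels alone the difference was 0.10 over 14 windows and lost the call (adjusted p = 0.0522). With normexp background correction it was -0.082, with the sign reversed. The Cy5 signal alone differed by 0.48, with 0.18 in series 1 and 0.79 in series 2. The input over the 83 probes differed by -0.10 in series 1 and 0.43 in series 2, so part of the Cy5 difference of series 2 came with the input.

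**Figure D3:**
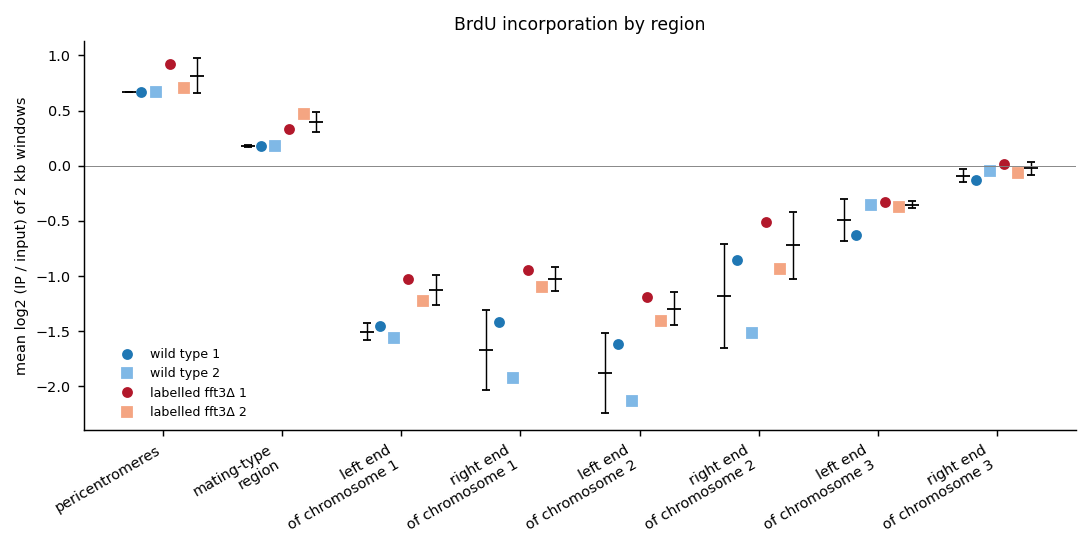
Mean log2 ratio of the 2 kb windows of each region (y axis) on each array (circles, series 1; squares, series 2; blue, wild type; red and orange, labelled fft3Δ), with black bars for the mean and SD of each group (n = 2). The pericentromeres lay above 0 on all 4 arrays, at 0.66 to 0.93, and the ends of chromosomes 1 and 2 below it, at -2.13 to -0.51.

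No single 2 kb window was called. Of 6234 windows, 0 passed an adjusted p of 0.05 in limma. An unadjusted p under 0.05 was found for 302, which is below the share of 0.05 expected with no change. Of these, 227 were higher and 75 lower in the arrays labelled fft3Δ. The higher ones included 62 of the 95 subtelomere windows. Outside peaks, the largest falls in moderated t, none past the threshold (adjusted p = 0.883 each), were at 2300001 to 2302000 of chromosome 2 (-0.63), 1408001 to 1410000 of chromosome 2 (-0.46) and 1304001 to 1306000 of chromosome 3 (-0.41). With the Cy5 signal alone they were -0.48, -0.13 and -0.11, and with normexp background correction -0.73, -0.73 and -0.49. Without wild-type array 2 the first was -0.41. With the scanner as a block, which here is the same as the series, 114 windows passed, 106 higher and 8 lower, 50 of them in the subtelomeres. Without wild-type array 1, 42 windows passed. In simulated data with the fitted spread, changes of 1 on the log2 scale were recovered in 95.1% of windows and changes of 0.5 in 12.9%. There 200 windows were changed, with independent errors, and so many changes ease the adjusted threshold. These rates do not show that a lone change of 1 would pass. In the arrays a difference of 0.96 had an adjusted p of 0.883 (limma).

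Local maxima of the BrdU signal, the candidate sites of early replication, were then compared. At 1 background SD over the median, 302 peaks were found on the mean of the 4 arrays, with a median spacing of 15.6 kb. The 5 tallest were at 1122301 and 1082101 of chromosome 3, both in its pericentromere, at 2117401 and 1269001 of chromosome 2, and at 3875101 of chromosome 1, with mean smoothed log2 ratios of 2.07, 1.67, 1.63, 1.604 and 1.59. With loess normalization these heights were 1.20, 0.90, 1.09, 0.91 and 0.88, and with the Cy5 signal alone 4.45, 3.90, 2.46, 2.97 and 2.96, so that their order changed. The median peak had a log2 ratio of 0.75 ± 0.02 in the arrays labelled fft3Δ and 0.83 ± 0.01 in wild type (SD, n = 2 each). This difference of -0.079 had the same sign in both series, and both labelled arrays lay below both wild-type arrays (exact permutation p = 0.33, the smallest possible), but it changed sign with loess normalization (0.027) and with the Cy5 signal alone (0.23). By peak, 201 were lower and 101 higher in the arrays labelled fft3Δ.

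None of the 302 peaks passed an adjusted p of 0.05 in limma, with 34 at an unadjusted p under 0.05, 25 of them lower and 9 higher. The 8 peaks with the largest falls in moderated t, not past the threshold, had differences between -0.42 and -0.64. They lay at 671701 and 573001 of chromosome 2, at 962401, 1688101 and 1572901 of chromosome 3, and at 1076401, 3868501 and 4075501 of chromosome 1. The lowest adjusted p among them was 0.092, for the peaks at 671701 of chromosome 2 (-0.54), 962401 of chromosome 3 (-0.64), 1076401 of chromosome 1 (-0.55) and 1688101 of chromosome 3 (-0.52). At 962401 of chromosome 3 the SD between arrays of a group was 0.48, whereas the moderated standard error, pooled over peaks, was 0.17. With the Cy5 signal alone, the difference of 7 of these 8 was positive, and with normexp background correction the falls were larger, from -0.80 to -1.10. Leaving out a single array moved 7 of the 8 by over 1.5 times. Without labelled fft3Δ array 1 the difference was -0.28 at 962401 and -0.26 at 1688101 of chromosome 3, -0.35 at 671701 and -0.26 at 573001 of chromosome 2, and -0.26 at 4075501 of chromosome 1. Without wild-type array 2 it was -0.32 at 962401 and -0.24 at 1572901 of chromosome 3, -0.29 at 1076401 of chromosome 1, and -0.285 at 573001 of chromosome 2. Without wild-type array 1 it was -0.96 at 962401 of chromosome 3, and without labelled fft3Δ array 2 -0.99 there and -0.79 at 1688101 of chromosome 3. The 8 with the largest rises, also not past the threshold, had differences between 0.30 and 0.52. They lay at 2069101, 826801, 1512601, 1814101 and 1860301 of chromosome 3, at 3300901 and 3579001 of chromosome 1, and at 2133301 of chromosome 2. Only the first of these had an adjusted p of 0.092. With normexp background correction the rises ranged from 0.031, at 3579001 of chromosome 1, to 0.42, at 826801 of chromosome 3, and that at 2069101 of chromosome 3 went from 0.52 to 0.14. With the Cy5 signal alone they ranged from 0.28, at 1814101 of chromosome 3, to 1.005, at 2069101 of chromosome 3. Without wild-type array 1 the rise was 0.31 at 2069101 and 0.18 at 1860301 of chromosome 3, and without wild-type array 2 0.19 at 1814101 of chromosome 3. Without labelled fft3Δ array 1 it was 0.33 at 2069101 of chromosome 3 and -0.014 at 2133301 of chromosome 2, and without labelled fft3Δ array 2 0.19 at 3579001 of chromosome 1 and 0.84 at 2133301 of chromosome 2. With the scanner as a block 7 peaks passed, 1 higher and 6 lower; leaving out a single array gave 6 without wild-type array 1, 1 without wild-type array 2, 0 without labelled fft3Δ array 1 and 9 without labelled fft3Δ array 2.

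The width of a peak at 50% of its height had a median of 3600 bp on wild-type array 1 and 3000 bp on wild-type array 2. On labelled fft3Δ arrays 1 and 2 it was 6900 bp and 4050 bp. This width depends on the peak's height and on the zero level of the ratio, and is not a length of BrdU tracts. At 4 to 5 kb from an apex the mean ratio was still 0.43 in both groups, so widths can reach into neighbouring signal. The mean difference of the medians was 2175 bp, larger than the SD of 424 bp in wild type but close to the SD of 2015 bp in the arrays labelled fft3Δ (exact permutation p = 0.33, the smallest possible). Labelled fft3Δ array 1 held most of it, and without that array the difference was 750 bp, and without labelled fft3Δ array 2 it was 3600 bp. None of the 302 peaks passed an adjusted p of 0.05 for width in limma; 34 had an unadjusted p under 0.05, 30 of them wider in the arrays labelled fft3Δ. The difference was -150 bp with loess normalization and 450 bp with centring on the mode.

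Around the peaks, the mean log2 ratio within 1 kb of an apex was 0.77 ± 0.02 in the arrays labelled fft3Δ and 0.83 ± 0.004 in wild type, whereas at 1 to 2 kb it was 0.57 ± 0.08 against 0.50 ± 0.03 (SD, n = 2 each). At 4 to 6 kb the groups had the same means within 0.001, and at 9 to 10 kb they reached 0.12 ± 0.02 and 0.15 ± 0.02. The exact permutation p was 0.33 for the first step and 0.667 for the second. The flank from 1 to 4 kb was higher by 0.048 in the arrays labelled fft3Δ, about the SD between arrays of 0.043, and differed by -0.059 with normexp background correction and by -0.038 with centring on the mode. Without labelled fft3Δ array 1 it was 0.0082, and without labelled fft3Δ array 2 0.088.

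**Figure D4:**
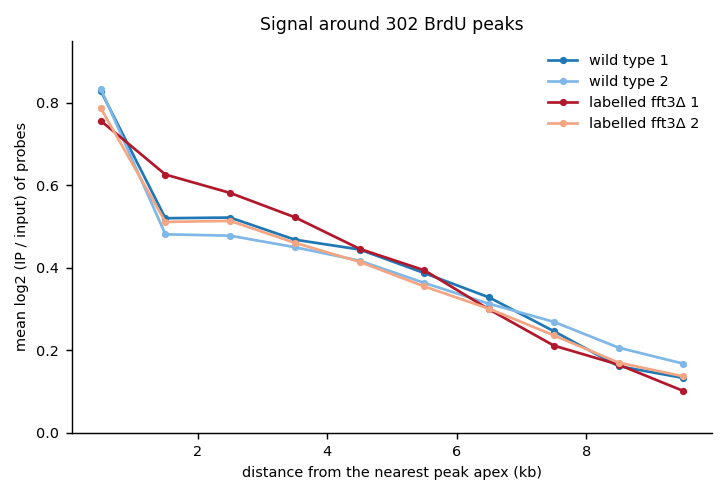
Mean log2 ratio of probes (y axis) by distance from the nearest of 302 peak apices (x axis, kb), with a line per array (blue, wild type; red and orange, labelled fft3Δ). Labelled fft3Δ array 1 started lowest, at 0.76, and was the highest at 1 to 2 kb, at 0.63.

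Called separately, 381 peaks were found on the mean of the wild-type arrays and 293 on the mean of the arrays labelled fft3Δ, and 181 of the wild-type peaks (47.5%) had a labelled fft3Δ peak within 2 kb. Positions drawn at random from the probes over the same threshold were shared for a median of 111 wild-type peaks, and for at most 129 in 1000 draws. The draws had no spacing rule, whereas a called peak is the highest probe within 5 kb on each side. Drawn positions can thus crowd together and reach fewer wild-type peaks, so these draws cannot show how far the sharing exceeds chance. With peaks over 1.5 background SDs, 106 and 67 were called and 31 shared. With normexp background correction 469 and 308 were called, whereas with loess normalization (379 and 389) and with the Cy5 signal alone (660 and 720) the arrays labelled fft3Δ had more. These counts have no test.

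DNA content was compared through the input in the same 2 kb windows. In limma, 0 of 6234 windows passed an adjusted p of 0.05 and 7 had an unadjusted p under 0.05, far below the share of 0.05 expected with no change. The inputs of the 2 wild-type arrays differed widely (correlation of 0.64), so the lack of calls says little about DNA content. Without wild-type array 2, 2 windows passed, and without wild-type array 1, which left wild-type array 2 against both arrays labelled fft3Δ, 2693 passed. Across probes, which are not independent replicates, the log2 input of wild-type array 2 correlated with that of the other arrays at 0.64 to 0.71, and the other 3 arrays with each other at 0.94 to 0.99. Its log2 input signals had an SD of 0.57, against 1.01 to 1.09 on the others, and its log2 Cy5 signals an SD of 0.87, against 1.29 to 1.36. The log2 ratios of the arrays did not group by genotype either: the highest correlation across probes was between wild-type array 1 and labelled fft3Δ array 2 (0.94), and that between the 2 wild-type arrays was 0.83.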

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

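The comparisons of these contigs in the Cy5 and input channels were chosen after the data were seen. The Cy5 signal of the pNSU contigs, which no comparison used, was higher on both arrays labelled fft3Δ (1.06 and 1.03 above the array median on the log2 scale) than on both wild-type arrays (0.79 and 0.91), a mean difference of 0.20. The ratio to input did not share this, being higher by 0.70 in series 1 and lower in series 2, at -0.99, where the input of wild-type array 2 stood apart.

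The Cy5 signal of the mitochondrial contig was 4.62 and 4.63 on the arrays labelled fft3Δ against 4.34 and 2.73 on the wild-type arrays, a mean difference of 1.09 that came mostly from wild-type array 2. The input of the same contig was 1.93 on wild-type array 2 and 4.27 to 5.08 on the others. No biological explanation was tested for either contig.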

How the results depend on the processing

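The peak thresholds of 1, 1.5 and 0.5 SDs, the probes without f or m and the chromosome 2 mating-type copy were chosen after the data were seen. The subtelomere difference stayed positive, and was called at the preset correlation under every other setting with a test, from 0.27 with the Cy5 signal alone to 0.74 without wild-type array 1, and 0.29 without wild-type array 2; the shared slide alone gave 0.41 with no test, and with an estimated correlation it lost the call (0.51, adjusted p = 0.146). The pericentromeres lost it in the same way (0.15, adjusted p = 0.250) and moved to 0.26 on the shared slide. The mating-type region lost it with an estimated correlation (0.22, adjusted p = 0.146) and with probes well above background in both channels (0.10, adjusted p = 0.0522), which left 14 of 20 windows, and reversed with normexp (-0.082, adjusted p = 0.595). It was 0.15 on the chromosome 2 copy (adjusted p = 0.0051). An f or m was in the names of 60 of 110 mating-type, 240 of 342 pericentromere and 285 of 587 subtelomere probes. Over the chromosomes and the mating-type contig it was in 1568 of 41361. Without them the mating-type difference was 0.35 over 8 windows (camera, preset correlation, adjusted p = 0.0015). The pericentromeres gave 0.11 over 16 windows (adjusted p = 0.0219) and the subtelomeres 0.56 over 49 (adjusted p = 1.3e-30).

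With the replicate block, 114 windows (106 higher, 8 lower) and 7 peaks were called in place of 0, and it changed no other call. Deviations of same-numbered arrays correlated at 0.37 over windows; with 2 pairs this is not evidence of pairing. Single probes gave 1 call. Leaving out each array gave 0 to 42 windows, 0 to 9 peaks and 0 to 2693 windows of input, where the lone array of a group was assumed to vary like the other group. Quantile normalization called 2 peaks. The Cy5 signal alone called 20 widths, 10 in each direction.

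The median peak difference of -0.079 moved to -0.29 with normexp, 0.027 with loess, -0.033 with SD scaling, -0.037 with quantile normalization, -0.16 with mode centring, 0.23 with Cy5 alone, -0.021 with peaks over 2 SDs and -0.14 with peaks of the wild-type arrays. The median width difference moved to -150 bp with loess, 450 bp with mode centring, 0 bp with Cy5 alone and 4050 bp over 1.5 SDs, and was 1050 bp over 0.5 SDs. The flank of the profile moved to -0.059 with normexp and -0.038 with mode centring. Shared peaks numbered 576 with Cy5 alone, 3 over 2 SDs, 31 over 1.5 SDs and 328 over 0.5 SDs. The cause was not tested.

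Of 324 values of named peaks and windows under alternatives, 47 moved by over 1 SD and 8 reversed. With Cy5 alone these were the peaks at 671701 (0.086) and 573001 (0.24) of chromosome 2, at 962401 (0.18) and 1572901 (0.33) of chromosome 3, and at 1076401 (0.19), 3868501 (0.53) and 4075501 (0.26) of chromosome 1. The peak at 2133301 of chromosome 2 ranged from -0.014 (without labelled fft3Δ array 1) to 0.84 when each array was left out. The cause was not tested. Not run were all settings of the gene lists and genes changed, the planned 3 and 5 SD thresholds, which left 0 peaks, and slide blocks for counts, which leave no test. The median signal over background was 17.1 times or more on every array in Cy3. Leaving out the probes not well above background in both channels changed only the mating-type call. The background correction mattered beyond that contig, since normexp moved the pericentromere difference from 0.15 to 0.009 and the median peak difference from -0.079 to -0.29.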

Other observations

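The tests of input range, single arrays and missing DNA below were chosen after their results had been seen; those of the Cy5 signal over subtelomeres, of matched interior windows and of rounding were fixed before. Some windows had a high input signal, for which no copy number was tested. The input of the outermost windows of the left end of chromosome 3 lay 3.25 to 5.44 above the array median on the log2 scale on wild-type array 1. On chromosome 1, windows 3362001 to 3364000 and 3364001 to 3366000 had inputs of 3.10 and 3.35 on that array, and the BrdU ratio stepped there from -1.74 to 0.51 on wild-type array 1 and by at least 2.17 on every array, the steepest of 6185 steps between adjacent windows, against a 99th percentile of 0.42.

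A stretch of chromosome 2, 690001 to 698000, combined such an input (2.75, 3.09, 0.86 and 2.52 on wild-type array 1, labelled fft3Δ array 1, wild-type array 2 and labelled fft3Δ array 2) with a lower BrdU ratio in the arrays labelled fft3Δ. The ratio over its 3 windows was 1.05 and 1.62 in wild type and 0.38 and 0.97 in the arrays labelled fft3Δ, a difference of -0.67 in series 1 and -0.65 in series 2. No window of it passed the adjusted threshold (limma, adjusted p = 0.883), and it was singled out after its values were seen. The input was higher in the arrays labelled fft3Δ by 0.34 in series 1 and 1.66 in series 2. A higher input by itself lowers the ratio, in series 2 by more than the ratio differed. The series 2 value cannot be read as particular to this stretch, because the input of wild-type array 2 read low at other high-input windows too. At 3362001 to 3364000 of chromosome 1 it was 1.37, against 2.74 on labelled fft3Δ array 2. Wild-type array 1 and labelled fft3Δ array 1 read 3.10 and 3.08 there.

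The less depleted chromosome ends in the arrays labelled fft3Δ were weighed against 3 technical explanations. A general rise of late-replicating DNA is argued against, since 95 interior windows matched on their mean ratio (-1.29) differed by -0.046, with 0.061 in series 1 and -0.15 in series 2, against 0.51 at the subtelomeres. Wild-type array 2 alone is argued against as the whole cause by a difference of 0.29 without it, with both arrays labelled fft3Δ above the remaining wild-type array. Less input DNA from the ends remains open: the Cy5 signal alone differed by 0.27 on average, by 0.29 in series 1 and 0.26 in series 2, while the input differed by -0.13 and -0.41, so that the input carried part of the ratio difference. An effect of the genotype is the biological hypothesis, which may account for these values but cannot be separated from the label doubt next described or from chance among 4 arrays.

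The absence of any missing stretch in the arrays labelled fft3Δ may have more than a single source. The 16 probes of the mating-type contig that were not well above background on any input show that a probe can read at background. They cannot decide whether the array is blind to missing DNA, because absent DNA and probes that do not hybridise look alike on all 4 arrays. A deletion as long as the gene in at least 50% of the DNA, lying outside the gaps between probes, is argued against by a lowest run of -0.45 in series 1. A mislabelled culture, a small or partial disruption and a position in a gap stay open, and were not tested.

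Wild-type array 2 stood apart from the other 3 arrays. The rounding of its file is argued against as the source, because rounding the other arrays alike moved their correlations by at most 4.7e-05. Its narrow input range is argued against as the whole source, because with Cy5 alone its highest correlation with another array was 0.91, under the lowest of 0.95 among the other 3. Its Cy5 range was narrow too (SD of 0.87 against 1.29 to 1.36), so a compression of both channels stays open, and values from Cy5 alone carry it. It was also far brighter before background subtraction, with a median Cy3 signal of 34917 against 5563.5 to 8581 on the others. Its median Cy5 signal was 33808 against 3389 to 5258.5. Whether this brightness goes with the narrow ranges was not tested. A different slide, software version and DNA preparation could each be involved and were not tested, nor was any biological explanation.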
